A study of Mus musculus with 18 samples.

How the data were processed

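The series held 18 sequencing libraries from 9 livers of male C57BL/6 mice, with 3 livers per diet: chow, a high-fat diet (HFD) and the high-fat diet with lycopene (HFD+LYC). The labels give 8 weeks of diet from 8 weeks of age and an age of 16 weeks at sampling. Each liver gave 1 library of total poly(A) RNA (mRNA) and 1 of poly(A) RNA from ribosome-nascent chain complexes (RNC), which the submitters pelleted through a sucrose cushion after lysis with cycloheximide. The deposited file names carry the same animal code for the mRNA and the RNC library of a diet and replicate number, so the 9 animals were taken as separate and each pair of libraries as 1 liver. Replicate numbers are not stated to link animals of different diets.

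Per the file headers, each library listed a read count, an RPKM value and the length of the longest transcript for each of 24,539 genes, with splice variants merged and RefSeq identifiers given. Per the submitters' processing notes, bases were called with bcl2fastq and the build was mm10, and reads were mapped to RefSeq RNA sequences; the aligner and its settings are not given in the sources used here. The deposited read counts were whole numbers, and their sums differed between libraries, so the counts were used for all tests. The deposited RPKM values were computed by the authors from the read count, the longest transcript length and a library total that was constant within each file. That total exceeded the sum of the listed counts, by 0.765% to 29.9% of the total, and no file lists the reads that make up the difference. RPKM values were not used for tests. Of the 24,539 gene symbols, 23,724 matched the RefSeq annotation GRCm38.p6, which gave the coordinates (GRCm38/mm10) and gene types.

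Listed reads ranged from 4533729 to 12742436 per library, so 3 reads stood for 0.235 to 0.662 CPM in a single library. A group with no read of a gene was set to a floor of 3 reads over the group for a bound on the fold change. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Between replicates, counts of genes with at least 10 CPM varied 26.1 to 232 times as much as counting error alone would give (chi-square per degree of freedom). Strand use is not given in the sources used here. Counts of near-identical genes, such as Hba-a1 and Hba-a2 or members of the Serpina1, Mup and Cyp2c families, of ribosomal protein genes with processed pseudogenes, and of genes that overlap another gene are uncertain for that reason.

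Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group (minimum count 10, minimum total count 15), scaled with TMM and fitted with the robust quasi-likelihood model, and a gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05. The 9 mRNA libraries (12,664 genes, 6 residual degrees of freedom, biological coefficient of variation 0.352) and the 9 RNC libraries (11,660 genes, 6 degrees of freedom, 0.524) were fitted apart, and each gave HFD against control, HFD+LYC against HFD and HFD+LYC against control. A model of diet, library kind and their interaction over all 18 libraries (12,872 genes, 12 degrees of freedom, 0.430) gave the change of the RNC to mRNA ratio and RNC against mRNA in control livers. Levels are TMM-scaled CPM of the fit used, so a gene's CPM differs between the RNC fit and the 18-library fit. TMM factors of the HFD+LYC RNC libraries were 0.428, 1.15 and 0.836 in the RNC fit. The first principal component held 49.3% of the variance in mRNA and 54.0% in RNC.

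Gene groups were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists within a comparison. The 39 lists of pathways, complexes and cell type markers were fixed before the data were examined, as were the comparisons, the tests, the naming rule and all alternatives except those said to be added. Of these lists, 38 had at least 5 tested members; the other was counted but not tested. Members were also adjusted over the list alone. Each list was tested again with an estimated correlation and with fry, which asks whether the genes of a list moved on balance one way and does not compare them with other genes. A gene was named by a rule: the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups, the 3 members with the smallest p in the direction of each passing list, and 30 chosen genes in the HFD against control and HFD+LYC against HFD comparisons; where no gene passed, the 3 with the smallest p in each direction. The text gives a part of those so named, the rest are not reported here, and it says where a gene or a test was chosen after its values were seen.

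The residuals of libraries were compared to see whether replicate numbers link them. For the mRNA and RNC library of the same liver, r across genes was -0.036 to 0.51, with 3 of 9 pairs over 0.1, against -0.52 to 0.38 with 3 of 18 for libraries of different livers. Across diets, libraries with the same number gave -0.42 to 0.46 in mRNA, with 7 of 9 over 0.1, and -0.063 to 0.33 in RNC, with 2 of 9. Libraries with different numbers had 4 of 18 over 0.1 in mRNA (-0.67 to 0.6) and 2 of 18 in RNC (-0.29 to 0.25); genes are not independent replicates. Blocks of replicate number were run as an alternative and not as part of the tests, although in mRNA same-number libraries were over 0.1 more often. The main tests of the 18-library model thus did not use the known pairing of the 2 libraries of a liver.

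Alternatives changed 1 choice at a time, except that DESeq2 changed scaling, dispersion and test together and limma-voom the model and test: RLE factors in place of TMM, DESeq2 1.42.0, limma-voom, other filters on low counts, a fit of only the compared libraries, a replicate block, limma on log ratios per liver, and each library left out in turn (both libraries of a liver in the 18-library model). Alternatives added after the data were seen were 1 surrogate variable (sva 3.50.0), a mean CPM of at least 50, leaving out genes with names that contain ribosomal, list tests on the compared libraries alone with a preset and with an estimated correlation, and list tests with the animal as a block. RLE and DESeq2 factors moved the median log2 change of all genes by 0.121 to 0.154 in the ratio of HFD+LYC against HFD or control and by -0.145 and -0.147 in control RNC against mRNA, and by less than 0.05 in the other comparisons. The tests were also run on simulated negative binomial counts with 200 changed genes, 67 at 2-fold, 67 at 4-fold and 66 at 8-fold, with the levels and spread of these libraries. Each comparison was repeated for all 10 splits of its 6 samples into 3 and 3. To count genes moved in opposite directions, simulated sets gave the count that the shared HFD libraries produce without a lycopene effect. Per library kind, 10 sets had no effect of either diet and 10 kept the HFD effect. The rule for an outlying sample needs at least 4 samples per group and was not applied to groups of 3.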

Results

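The study measured liver RNA of male C57BL/6 mice fed normal chow (control), a high-fat diet (HFD) or the high-fat diet with lycopene, a tomato carotenoid (HFD+LYC), for 8 weeks from 8 weeks of age. From each of 9 livers, 3 per diet, poly(A) RNA was sequenced from total RNA (mRNA) and from RNA bound to ribosome-nascent chain complexes (RNC), which gave 18 libraries. Each library listed read counts for 24,539 genes, of which 6,956 had 0 reads in every library. The mRNA libraries held 9022252, 6500148 and 8659161 counted reads in control, 9788785, 7684372 and 11613078 in HFD, and 6586080, 5806647 and 9136396 in HFD+LYC livers. The RNC libraries held 9429838, 11712137 and 12036487 reads in control, 5535100, 11794164 and 12742436 in HFD, and 11300925, 4533729 and 8944808 in HFD+LYC livers. Levels below are CPM, read counts scaled to library size, given as mean ± SD over 3 livers (n = 3). Adjusted p-values come from edgeR's quasi-likelihood test.

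Between 13,791 and 15,332 genes had a read in each mRNA library, and between 13,324 and 14,450 in each control or HFD RNC library. The 3 HFD+LYC RNC libraries stood apart, with reads from 8940, 9567 and 10,037 genes in replicates 1, 2 and 3, and replicate 1 held 11300925 reads. In these 3 libraries 70 to 112 genes had exactly 1 read, against 614 to 861 in the other RNC libraries. The 10 most abundant genes took 31.9% to 47.3% of their reads, a range that overlapped the 25.7% to 34.2% in HFD and 28.6% to 32.5% in control RNC libraries. HFD+LYC mRNA replicate 2 had 189 genes with 1 read and reads from 13,791 genes.

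**Figure D1:**
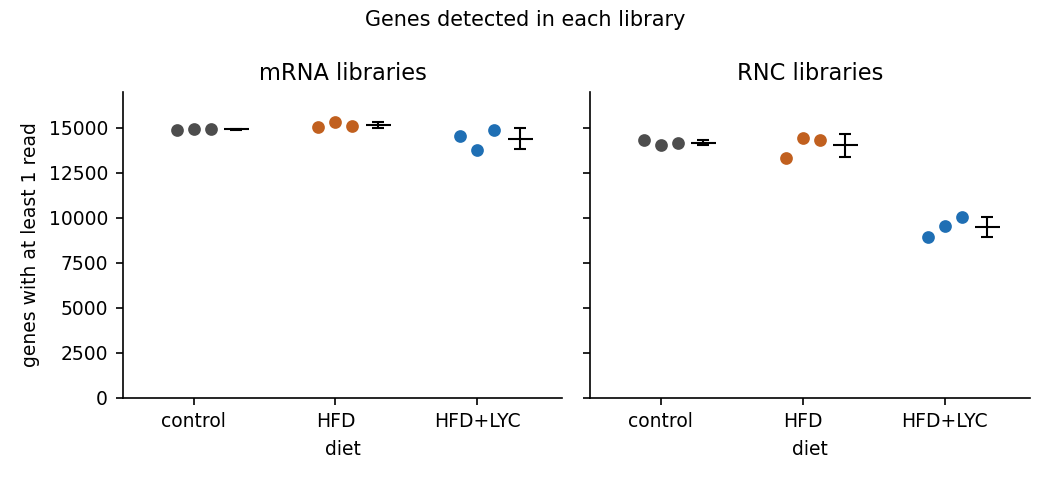
Genes with at least 1 read (vertical axis, number of genes) by diet (horizontal axis) in mRNA libraries (left) and RNC libraries (right); each dot is a library and each black bar the mean ± SD (n = 3). The 3 HFD+LYC RNC libraries lie between 8940 and 10,037 genes, and the other 15 libraries between 13,324 and 15,332.

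Which liver transcripts the high-fat diet moved was asked from mRNA in HFD against control livers. Mfsd2a, a transporter of lysophosphatidylcholine lipids, rose 79.8-fold, from 2.33 ± 0.603 to 187 ± 93.6 CPM (n = 3; log2 fold change 6.32, SE 0.553, adjusted p = 0.00145; chromosome 4, 122946850 to 122961194). Dbp, a clock-controlled transcription factor, rose 16.2-fold, from 1.36 ± 0.271 to 22.3 ± 11.3 CPM (adjusted p = 0.0122; chromosome 7, 45705100 to 45710203). Both were higher in all 3 HFD livers than in any control liver. Genes of fatty acid and triglyceride synthesis rose as a list, with 24 of 25 members above control and a median log2 change of 0.79 (camera, adjusted p = 2.27e-15; adjusted p = 0.183 with an estimated correlation). Of these 25, 6 were called higher when adjusted over the list alone and 25 were not called over all genes. The list held Elovl6, a fatty acid elongase, at 129 ± 37.6 against 44.8 ± 15.6 CPM, and Pnpla3, a triglyceride hydrolase, at 31.3 ± 17.3 against 4.57 ± 1.88 CPM.

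**Figure D2:**
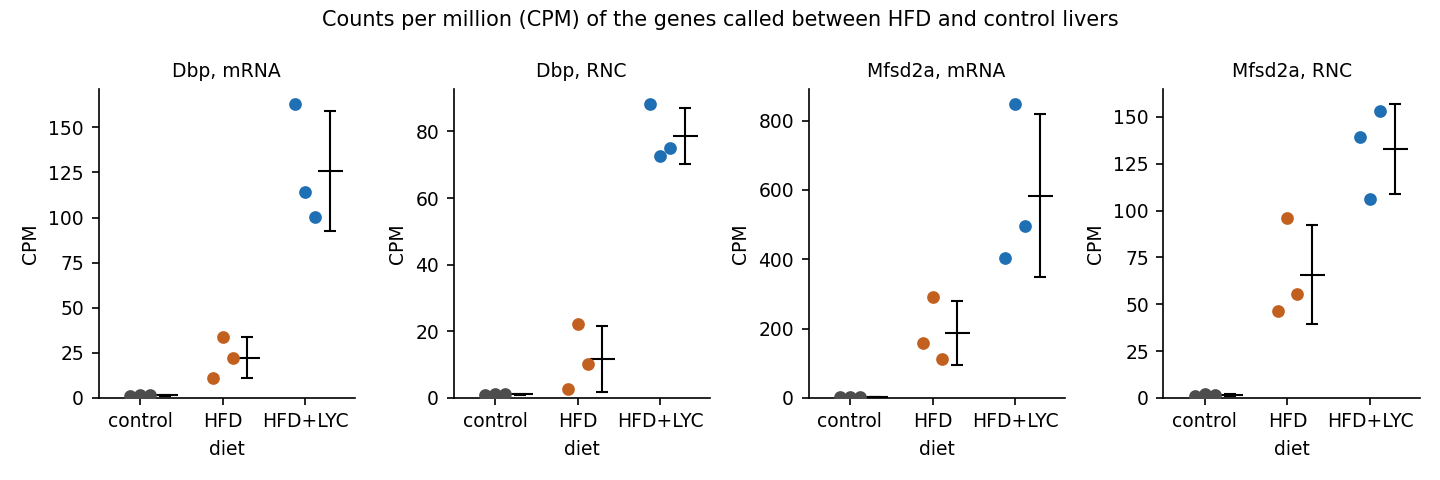
Levels of Dbp and Mfsd2a (vertical axes, CPM) by diet (horizontal axis) in mRNA and in RNC libraries; each dot is a library and each black bar the mean ± SD (n = 3). In mRNA both genes were higher in all 3 HFD livers than in any control liver.

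Fatty acid oxidation genes also rose as a list in HFD mRNA, with 38 of 40 above control, 4 called higher when adjusted over the list alone and a median of 0.69 (adjusted p = 0.213 with an estimated correlation). Among them, Fgf21, a fasting-induced liver hormone, stood at 13.9 ± 2.74 against 2.26 ± 2.33 CPM, and Vnn1, a PPARα target, at 107 ± 5.86 against 33.0 ± 11.9 CPM (neither called). Lipid droplet and fatty acid uptake genes rose, with 20 of 24 above control, 2 called over the list alone and a median of 0.47 (adjusted p = 0.19 with an estimated correlation). The fatty acid transporter Cd36 stood at 91.7 ± 28.9 against 24.8 ± 13.95 CPM and the droplet protein Cidec at 6.84 ± 2.77 against 0.662 ± 0.474 CPM. Apoa4, of the apolipoprotein list, stood at 1071 ± 523 against 102 ± 62.3 CPM. None of these passed. Female-biased liver genes rose, with 9 of 10 above control, 7 called over the list alone and a median of 2.45, or 1.76 with its 2 members at 0 in a group set to the floor of 3 reads per group (adjusted p = 0.183 with an estimated correlation). The steroid hydroxylase Cyp17a1 stood at 21.2 ± 16.1 against 0.924 ± 0.226 CPM (adjusted p = 0.0684). Male-biased genes controlled by growth hormone fell, with 18 of 22 below control and a median of -0.48 (adjusted p = 0.478 with an estimated correlation). Markers of Kupffer cells, the liver macrophages, rose as a list with 21 of 24 above control and a median of 0.51 (adjusted p = 0.478 with an estimated correlation). Immediate early genes fell, with 16 of 19 below control and a median of -0.25 (adjusted p = 0.19 with an estimated correlation). Junb, a stress-induced transcription factor, stood at 30.5 ± 6.63 against 92.9 ± 35.6 CPM.

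Of 12,664 genes tested in HFD against control mRNA, 2 were called higher and 0 lower by edgeR. An unadjusted p under 0.05 was found for 358, where chance gives 633.2. In this comparison 7.22% had no overlap between the groups, where chance gives 10%. DESeq2 called 28 higher and 13 lower, limma-voom and a fit of the 6 compared libraries alone called 1, edgeR without a filter on low counts 6 and with 1 surrogate variable, added after the data were seen, 7. Dbp lost its call without control replicate 1, 2 or 3 (adjusted p = 0.136, 0.0829 and 0.165; 1 call left each time). Of 38 lists with at least 5 tested genes, 17 passed and 0 did with an estimated correlation; fry called 0. In simulated libraries with 12,664 genes, this comparison recovered 8.96% of 2-fold, 70.2% of 4-fold and 98.5% of 8-fold changes.

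In ribosome-bound RNA, HFD against control gave Mfsd2a as the only call, 49.5-fold higher at 65.9 ± 26.4 against 1.31 ± 0.517 CPM (log2 fold change 5.63, SE 0.429, adjusted p = 0.00238). Fatty acid and triglyceride synthesis genes rose as a list, with 21 of 25 above control, 7 called higher over the list alone and a median of 0.69. It had adjusted p = 0.0115 with an estimated correlation over all 9 RNC libraries, but adjusted p = 0.2655 with an estimated correlation on the 6 compared libraries alone, a fit chosen after the data were seen. The fatty acid elongase Elovl5 stood at 1451 ± 418 against 419 ± 86.2 CPM, malic enzyme Me1 at 540 ± 149 against 201 ± 51.5 CPM and fatty acid synthase Fasn at 423 ± 68.1 against 179 ± 40.7 CPM, with none called over all genes. Lipid droplet and uptake genes rose as well, with 19 of 24 above control, 5 called over the list alone and a median of 0.49 (adjusted p = 0.0115 with an estimated correlation, 0.2655 on the 6 libraries alone). Cd36 stood at 108 ± 61.6 against 22.6 ± 9.58 CPM. Apoa4, of the apolipoprotein list, stood at 652 ± 236 against 61.3 ± 10.7 CPM (adjusted p = 0.343). Genes of glucose metabolism and insulin response rose, with 17 of 24 above control and a median of 0.33 (adjusted p = 0.0478 with an estimated correlation, 0.2655 on the 6 libraries alone).

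Fatty acid oxidation genes had 37 of 40 members above control in HFD RNC and a median of 0.55 (adjusted p = 0.0725 with an estimated correlation). Male-biased genes had 20 of 21 below control and a median of -0.68 (adjusted p = 0.158 with an estimated correlation). All 24 tested Kupffer cell markers lay above control with a median of 0.42 (adjusted p = 0.158 with an estimated correlation). Erythroid markers fell, with a median of -0.57 over 5 members (camera, adjusted p = 6.85e-05, or 0.2655 with an estimated correlation on the 6 libraries alone), and had -0.40 in mRNA. Female-biased genes had 7 of 8 called higher over the list alone and a median of 3.81 (adjusted p = 0.069 with an estimated correlation). Cytochrome P450 genes of xenobiotic metabolism fell by camera with a median of -0.31 over 31 members, but their mean was 0.04 (adjusted p = 0.309 with an estimated correlation). Among these, Cyp3a11, a steroid and drug hydroxylase, stood at 1685 ± 115 against 4307 ± 1560 CPM and Cyp2c70, which makes muricholic acids, at 160 ± 5.87 against 459 ± 104 CPM; neither was called.

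Of 11,660 genes tested in HFD against control RNC, 1 was called higher and 0 lower. An unadjusted p under 0.05 was found for 214, where chance gives 583. Between the groups 14.2% had no overlap (chance 10%). DESeq2 called 33, limma-voom 0, a fit of the 6 libraries alone 32 and edgeR 4 among genes with a mean CPM of at least 50, a limit set after the data were seen. Without control replicate 3 no call was left (Mfsd2a, adjusted p = 0.0583), and without HFD replicate 1 or HFD+LYC replicate 2 there were 2. Of 38 lists, 19 passed and 3 with an estimated correlation, and on the 6 libraries alone 20 passed and 0 with an estimated correlation. Simulated libraries with 11,660 genes gave back 1.49% of 2-fold, 23.9% of 4-fold and 60.6% of 8-fold changes.

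How far ribosome-bound RNA followed total RNA under the high-fat diet was asked across genes, which are not independent replicates. The HFD log2 changes in mRNA and RNC correlated at r = 0.600 (Spearman's rho = 0.399) over 11,572 genes. Mfsd2a was called in both, Dbp in mRNA alone (11.6 ± 9.85 against 1.03 ± 0.0739 CPM in RNC). In all, 90 genes had an unadjusted p under 0.05 in both, all with the same sign; the mRNA and RNC libraries came from the same 6 livers. The other splits of these livers gave r up to 0.594, and 10 splits are too few for a share under 0.05. Without control replicate 1 the correlation was 0.401, and without HFD replicate 2 it was 0.299.

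Whether the diet changed the share of a transcript on ribosomes was tested as the RNC to mRNA ratio, in a model over all 18 libraries. For HFD against control edgeR called 0 of 12,872 genes. An unadjusted p under 0.05 was found for 20 genes, where chance gives 643.6. The test was thus conservative here, and 0 calls do not show that the ratio was unchanged. DESeq2 called 1 lower, limma-voom 0 and limma on log ratios per liver 0. Among the genes nearest to a call, Trem2, a lipid-sensing macrophage receptor, stood at 1.76 ± 0.555 against 0.386 ± 0.203 CPM in RNC and at 1.04 ± 0.198 against 1.22 ± 0.602 CPM in mRNA. The ratio fell by camera for 5 lists and rose for 1. Heat shock proteins had 13 of 16 members below 0 and a median of -0.24, and unfolded protein response genes 25 of 34 and a median of -0.27. Translation factors had 35 of 45 below 0 and a median of -0.11, amino acid breakdown genes 26 of 36 and a median of -0.11, and mitochondrial ribosomal proteins 51 of 76 and a median of -0.087. Host genes of small nucleolar RNAs had 14 of 17 above 0 and a median of 0.57. All 6 calls were lost when correlation was estimated (adjusted p = 0.937 with an estimated correlation for each). With the 2 libraries of an animal as a block, 14 lists passed in place of 6. Of the tested genes, 4.99% had no overlap (chance 10%). Simulated libraries with 12,872 genes recovered 1.49%, 10.4% and 47.0% of 2-fold, 4-fold and 8-fold changes of the ratio.

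What lycopene added to the high-fat diet was asked from HFD+LYC against HFD livers. In mRNA, Ciart, a repressor of the clock, rose 88.6-fold to 125 ± 40.1 from 1.43 ± 1.30 CPM (SE 0.612 on the log2 scale, adjusted p = 0.00146). Usp2, a rhythmic deubiquitinase, rose 48.5-fold to 115 ± 23.4 from 2.38 ± 1.51 CPM (adjusted p = 0.00146). Dbp rose by 2.50 on the log2 scale to 126 ± 33.1 CPM (adjusted p = 0.0125). Npas2, a partner of the clock protein Bmal1, fell 15.6-fold to 0.353 ± 0.418 from 5.79 ± 4.04 CPM (adjusted p = 0.0212). Of 19 clock genes, 8 were higher, 2 lower and 9 not called (12 called over the list alone), with a median of 1.36 (camera, adjusted p = 2.65e-07; adjusted p = 0.614 with an estimated correlation). The time of day at which the livers were taken is not given in the sources used here. In control livers Ciart stood at 0.530 ± 0.139 CPM and Dbp at 1.36 ± 0.271 CPM. The 9 clock genes that peak in the evening exceeded the 5 that peak in the morning by 3.49 to 4.26 in mean log2 CPM in HFD+LYC livers, in the plot of clock genes by diet, whose genes were chosen after the values were seen.

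**Figure D3:**
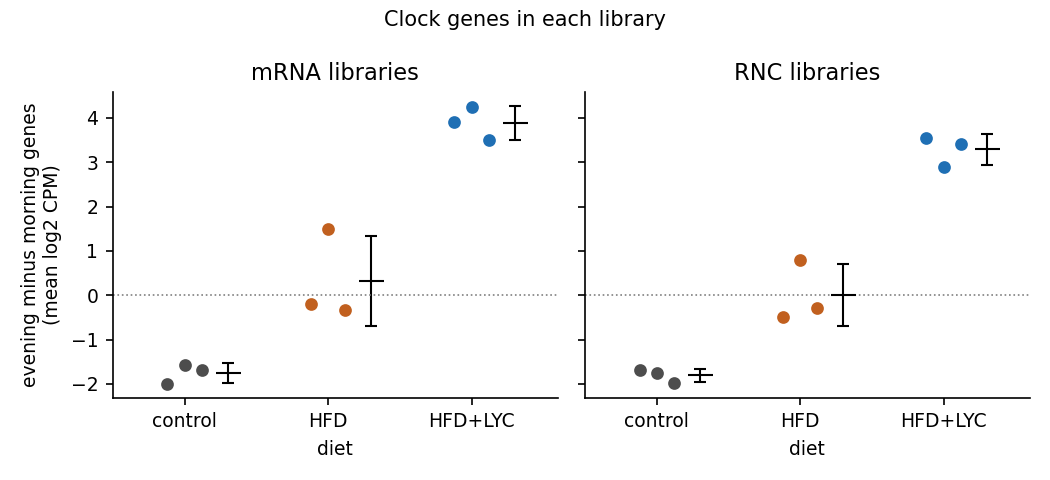
Mean log2 CPM of 9 clock genes that peak in the evening minus that of 5 that peak in the morning (vertical axis) by diet (horizontal axis) in mRNA (left) and RNC libraries (right); each dot is a library, each black bar the mean ± SD (n = 3) and the dotted line is at 0. In mRNA the difference was -2.00, -1.58 and -1.68 in control, -0.21, 1.48 and -0.33 in HFD and 3.91, 4.26 and 3.49 in HFD+LYC libraries.

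Of 36 genes of amino acid breakdown and the urea cycle, 3 were higher and 33 not called in HFD+LYC against HFD mRNA (6 higher over the list alone), with a median of 0.26 (adjusted p = 0.863 with an estimated correlation). Sdsl and Sds, which deaminate serine and threonine, rose 6.11-fold to 50.4 ± 19.1 CPM (adjusted p = 0.00621) and 5.38-fold to 1091 ± 770 CPM (adjusted p = 0.0326). The urea cycle enzyme Asl rose 3.99-fold to 1555 ± 279 CPM (adjusted p = 0.0372). Cholesterol synthesis genes fell as a list, with 22 of 25 below HFD and a median of -0.83 (adjusted p = 0.94 with an estimated correlation). All 25 missed the threshold over all genes and 7 were lower over the list alone. Hmgcs1, an early enzyme of the pathway, stood at 208 ± 50.1 against 693 ± 181 CPM (adjusted p = 0.0562) and Sqle, squalene epoxidase, at 7.04 ± 4.18 against 39.4 ± 33.7 CPM (adjusted p = 0.0567). Kupffer cell markers fell, with 23 of 24 below HFD, 2 called lower (7 over the list alone) and a median of -1.03 (adjusted p = 0.863 with an estimated correlation). The lysosomal protease Ctss fell by 1.82 on the log2 scale to 8.80 ± 0.777 CPM (adjusted p = 0.0278) and the complement receptor Vsig4 5.67-fold to 3.81 ± 2.14 CPM (adjusted p = 0.0449). Among interferon response genes, Ifi47, a GTPase, fell 2.75-fold to 9.42 ± 2.35 CPM (adjusted p = 0.0319). In this list 1 of 28 was higher, 1 lower and 26 were not called, with a median of -0.41 (adjusted p = 0.847 with an estimated correlation).

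Avpr1a, a vasopressin receptor, fell 7.96-fold to 5.86 ± 0.903 from 46.7 ± 11.3 CPM in HFD+LYC mRNA (adjusted p = 0.00146). Snhg3 and Snhg20, host genes of small nucleolar RNAs, rose 5.37-fold to 65.0 ± 13.4 CPM (adjusted p = 0.00621) and 4.31-fold (adjusted p = 0.0413). Of 17 such hosts 2 were higher and 15 not called, with a median of 0.67 (adjusted p = 0.847 with an estimated correlation). Other lists that fell were the proteasome (26 of 31 below HFD, median -0.34), glutathione and NRF2 genes (30 of 39, median -0.54), oxidative phosphorylation (53 of 77, median -0.28) and mitochondrial ribosomal proteins (53 of 76, median -0.28), each with adjusted p = 0.94 with an estimated correlation and no single call. Immediate early genes rose with a median of 0.79 (adjusted p = 0.771 with an estimated correlation). Of these 19 genes 1 was called higher, Ier3, an early stress-response gene, 4.99-fold (adjusted p = 0.0288). Erythroid markers rose with a median of 1.28 over 5 members, 3 of them higher over the list alone (adjusted p = 0.847 with an estimated correlation). Haemoglobin Hba-a1 stood at 142 ± 47.6 against 40.3 ± 28.6 CPM. Fatty acid and triglyceride synthesis genes had 4 of 25 higher and 21 not called (median -0.52) and lipid droplet genes 1 of 24 higher and 23 not called (median 0.12), and neither list passed. Genes that cleave carotenoids were not called: Bco1 stood at 9.38 ± 3.29 against 5.44 ± 1.10 CPM and Bco2 at 27.8 ± 4.42 against 37.2 ± 6.01 CPM. Neither Plin2 nor Cidec was called, with the droplet coat protein Plin2 at 163 ± 69.7 against 525 ± 295 CPM (adjusted p = 0.0733) and the droplet protein Cidec at 46.4 ± 35.2 against 6.84 ± 2.77 CPM (adjusted p = 0.0613).

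Of 12,664 genes, 252 were called higher and 116 lower in HFD+LYC against HFD mRNA, and 31.9% had no overlap (chance 10%). DESeq2 called 871 higher and 620 lower, a block of replicate number 852 higher and 605 lower, and a fit with 1 surrogate variable, added after the data were seen, 907 in all. The count of 368 was 606 without control replicate 2, 161 without control replicate 3, 104, 84 and 72 without HFD replicates 1, 2 and 3, and 66 without HFD+LYC replicate 1 or replicate 2. Of the 26 named genes that passed, the calls lost were 2 and 7 without control replicates 1 and 3, 12, 13 and 17 without HFD replicates 1, 2 and 3, and 17, 16 and 6 without HFD+LYC replicates 1, 2 and 3. Ciart, Usp2, Dbp, Sdsl, Snhg3 and Avpr1a kept theirs without any single library. Vsig4 lost its call without control replicate 1 (adjusted p = 0.0543), Asl, Ifi47, Sds, Snhg20 and Vsig4 without control replicate 3 (adjusted p 0.0595 to 0.0724), and Asl, Ier3, Ifi47, Npas2, Sds and Snhg20 without HFD replicate 1 (0.0561 to 0.0939). Asl, Ctss, Ier3, Sds, Snhg20 and Vsig4 lost theirs without HFD replicate 2 (0.0551 to 0.114), these and Ifi47 without HFD replicate 3 (0.0822 to 0.122) or HFD+LYC replicate 2 (0.0719 to 0.125), these and Npas2 without HFD+LYC replicate 1 (0.0616 to 0.125), and Asl, Ctss, Ifi47, Npas2 and Vsig4 without HFD+LYC replicate 3 (0.0506 to 0.0673). The log2 changes of Ciart and Usp2 were 7.43 and 6.23 without HFD replicate 2 in place of 6.47 and 5.60. Npas2 had -3.21 without HFD replicate 1 and -5.30 without HFD+LYC replicate 2 in place of -3.96, and Sds had 1.68 without HFD+LYC replicate 2 in place of 2.43. Simulated libraries recovered 10.4%, 73.1% and 95.5% of 2-fold, 4-fold and 8-fold changes over 12,664 genes. Of 38 lists, 12 passed and 0 with an estimated correlation; fry called 2.

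HFD+LYC against control livers compared lycopene-fed mice with the chow baseline. In mRNA, Mfsd2a rose 249-fold to 583 ± 235 CPM (SE 0.591, adjusted p = 0.00016). Lpin1, which makes diacylglycerol and co-activates fat oxidation genes, rose 25.02-fold to 559 ± 184 from 22.3 ± 5.74 CPM (adjusted p = 0.000398). Elovl6 reached 581 ± 54.9 CPM (adjusted p = 0.000958) and Thrsp, a regulator of lipid synthesis, rose 8.18-fold to 1476 ± 327 CPM (adjusted p = 0.00907). Of 25 fatty acid and triglyceride synthesis genes 4 were higher and 21 not called (5 over the list alone; median 0.56; adjusted p = 0.643 with an estimated correlation). Lipid droplet genes had 7 of 24 higher and 17 not called, with a median of 0.68 (adjusted p = 0.643 with an estimated correlation). Cidec rose 68.7-fold (adjusted p = 0.00553) and the droplet coat Plin4 17.01-fold to 272 ± 235 CPM (adjusted p = 0.012). Cholesterol synthesis genes fell, with 4 of 25 lower and 21 not called (11 lower over the list alone), a median of -0.95 (adjusted p = 0.643 with an estimated correlation). Sqle was 6.28-fold lower (adjusted p = 0.0354) and Hmgcs1 3.70-fold lower (adjusted p = 0.0321).

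Clock genes had 10 of 19 higher, 3 lower and 6 not called in HFD+LYC against control mRNA, with a median of 1.20 (adjusted p = 0.157 with an estimated correlation). Ciart rose 231-fold, Dbp 91.3-fold and Usp2 60.0-fold, and Npas2 fell 54.0-fold. Glucose metabolism genes had 6 of 24 higher and 18 not called (median 0.70; adjusted p = 0.157 with an estimated correlation). Pfkfb3, which makes an activator of glycolysis, rose 5.59-fold (adjusted p = 0.00341). Amino acid genes had 7 of 36 higher and 29 not called (median 0.33; adjusted p = 0.643 with an estimated correlation). Fatty acid oxidation genes had 6 of 40 higher and 34 not called (median 0.35; adjusted p = 0.643 with an estimated correlation). Female-biased genes had 3 of 10 higher and 7 not called (median 2.61; adjusted p = 0.643 with an estimated correlation). Cyp17a1 rose 25.8-fold (adjusted p = 0.00434) and Cyp2b10, a phenobarbital-inducible P450, with 0 reads in control livers, was at least 25.9-fold higher. Male-biased genes had 21 of 22 below control and no call (median -1.19; adjusted p = 0.643 with an estimated correlation). Cyp3a59 fell 20.3-fold to 4.70 ± 1.13 from 95.6 ± 31.8 CPM (adjusted p = 0.00309). Endothelial markers had 5 of 21 higher and 16 not called (median 0.22), such as the scavenger receptor Stab1 3.42-fold (adjusted p = 0.0292). Cholangiocyte markers had 2 of 10 lower and 8 not called (median -0.48), Spp1 4.00-fold (adjusted p = 0.00569) and Sox9 4.59-fold (adjusted p = 0.0121). Both lists had adjusted p = 0.643 with an estimated correlation. Camera also called Kupffer cell markers (median -0.63), long non-coding RNAs (-0.54), cytosolic ribosomal proteins (-0.455), complement and coagulation (-0.455), interferon response (-0.37) and the proteasome (-0.28) lower. It called cytosolic heat shock proteins higher (median 0.49), and 0 of these lists passed with an estimated correlation.

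HFD+LYC against control mRNA gave 419 higher and 282 lower of 12,664 genes, with 28.0% without overlap (chance 10%). DESeq2 called 1628, the replicate block 812 higher and 613 lower, and the fit with 1 surrogate variable 1914. The count of 701 was 227 without control replicate 1, 91 without control replicate 3, 462 without HFD replicate 2, and 236 and 271 without HFD+LYC replicates 1 and 2. Of 45 named calls, 12, 2 and 28 were lost without control replicates 1, 2 and 3, 4 without HFD replicate 1 or 2, and 13, 14 and 8 without HFD+LYC replicates 1, 2 and 3. In all 16 held in every alternative, among them Mfsd2a, Lpin1, Elovl6, Ciart, Usp2, Dbp, Npas2, Cyp17a1 and Spp1. Hmgcs1, Sqle and Stab1 lost theirs without control replicate 1 (adjusted p 0.104 to 0.107), these with Plin4, Sox9 and Thrsp without control replicate 3 (0.0559 to 0.114), Hmgcs1 without HFD replicate 1 (0.0511), and Hmgcs1, Sqle and Stab1 without HFD+LYC replicate 1 (0.0631 to 0.125) or 2 (0.0898 to 0.109). The log2 changes were 3.63 in place of 3.03 for Thrsp and 6.81 in place of 6.10 for Cidec without control replicate 1. They were -7.09 in place of -5.75 for Npas2 and 3.12 in place of 4.09 for Plin4 without HFD+LYC replicate 2. Simulated libraries with 12,664 genes recovered 10.4%, 73.1% and 98.5% of 2-fold, 4-fold and 8-fold changes. Of 38 lists, 18 passed and 0 with an estimated correlation.

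Whether lycopene moved back what the diet had moved was counted as genes called in HFD against control and called with the opposite sign in HFD+LYC against HFD. In mRNA the count was 0 by edgeR: of Mfsd2a and Dbp, the latter rose again with lycopene. In RNC the count was 0 as well, from the 1 gene called for HFD, with Mfsd2a at 139.5, 106 and 153 CPM in the 3 HFD+LYC libraries. If calls in the 2 comparisons were independent, 0.0183 genes in mRNA and 0.174 in RNC would be counted. The counts of 0 thus say little about a reversal. At an unadjusted p under 0.05 in both comparisons, 66 mRNA genes moved in opposite directions and 64 in the same direction. Simulated groups gave 131.7 opposite with no effect of either diet and 166 with the HFD effect kept and no lycopene effect. In RNC 75 genes moved in opposite and 52 in the same direction, against 127.9 and 144.1 in these 2 simulations. The real HFD against control tests had fewer genes under this limit than chance gives, 358 against 633.2 in mRNA and 214 against 583 in RNC. Real counts under this limit can thus fall below simulated ones for that reason alone, and no conclusion on a reversal is drawn from them. The covariance of the log2 changes was -0.0686 in mRNA and -0.100 in RNC. Simulated covariances were -0.110 and -0.334 with no effect of either diet, and -0.111 and -0.3305 with the HFD effect kept, as both comparisons share the HFD libraries. The 3 libraries cannot be split into parts of at least 2.

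In ribosome-bound RNA, ribosomal protein mRNAs were lower in HFD+LYC than in HFD livers. The 3 HFD+LYC libraries had reads from 8940 to 10,037 genes and those of HFD from 13,324 to 14,450. All 80 cytosolic ribosomal protein genes fell, with a median of -4.10, or -4.08 with 1 member at 0 in HFD+LYC set to its floor (adjusted p = 0.0277 with an estimated correlation, but 0.0804 on the 6 compared libraries alone). Rpl10 fell 52.2-fold from 449 ± 75.9 CPM (SE 0.314, adjusted p = 1.43e-05) and Rps6 27.1-fold to 11.9 ± 7.95 from 322 ± 32.4 CPM (adjusted p = 0.000149). Of 76 mitochondrial ribosomal protein genes 73 fell and 3 were not called (74 over the list alone), with a median of -4.96 with or without its 10 members at 0 set to the floor (adjusted p = 0.0277 with an estimated correlation, but 0.0804 on the 6 libraries alone). Mrps33 had 0 reads in HFD+LYC livers against 64.4 ± 4.97 CPM in HFD livers, at least 376-fold lower. The translation elongation factor Eef1a1 fell 2.65-fold (adjusted p = 0.00852). Another 20 tested genes whose names contain the word ribosomal but that encode no ribosomal protein had a median of -4.04, while ribosomal proteins listed under other names had Rack1 at 0.28, Fau at -2.48, Dap3 at -0.70 and Gadd45gip1 at 1.42. These groups by name were formed after the values were seen.

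**Figure D4:**
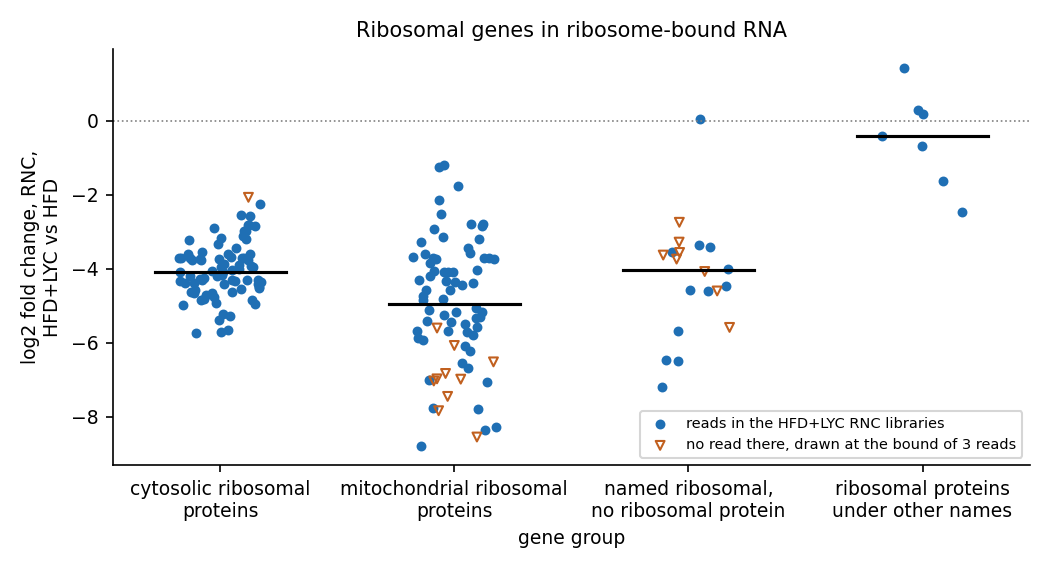
Log2 change in RNC, HFD+LYC against HFD (vertical axis), for groups of genes by name and function (horizontal axis). Each dot is a gene, each triangle a gene with no read in HFD+LYC drawn at its bound from 3 reads, and each bar the group's median; cytosolic ribosomal proteins lie at a median near -4.10 and genes named ribosomal that encode no ribosomal protein at -4.04.

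In HFD+LYC against HFD RNC, in the libraries with reads from 8940 to 10,037 genes, 16 of 23 apolipoprotein and lipoprotein genes were higher, 1 lower and 6 not called, with a median of 1.74 (adjusted p = 0.484 with an estimated correlation). Apoa1, the main protein of high-density lipoprotein, rose 10.4-fold to 72200 ± 50140 from 6967 ± 1590 CPM (adjusted p = 0.00265), Lcat, which esterifies plasma cholesterol, by 2.69 on the log2 scale (adjusted p = 0.00244) and Apoa4 6.78-fold (adjusted p = 0.00461). Complement and coagulation genes had 19 of 34 higher and 15 not called, with a median of 1.67 (adjusted p = 0.637 with an estimated correlation), such as prekallikrein Klkb1, 3.72-fold to 509 ± 93.3 CPM (adjusted p = 0.000684). Hepatocyte secretory genes had 11 of 18 higher, 1 lower and 6 not called (median 1.74; adjusted p = 0.484 with an estimated correlation), with fetuin Ahsg 7.56-fold higher (adjusted p = 0.00428). Acute phase genes had 7 of 28 higher and 21 not called (median 1.10; adjusted p = 0.637 with an estimated correlation), with haptoglobin Hp 7.97-fold higher (adjusted p = 0.0037). Autophagy and lysosome genes had 10 of 30 higher, 3 lower and 17 not called (median 0.72; adjusted p = 0.484 with an estimated correlation), with the glycogen-degrading Gaa 6.23-fold higher (adjusted p = 0.00106).

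Against HFD RNC, and again in HFD+LYC libraries with reads from 8940 to 10,037 genes, Lpin1 rose 31.6-fold to 524 ± 95.2 from 16.6 ± 1.46 CPM (adjusted p = 8.3e-05), Elovl6 8.93-fold to 623 ± 108 CPM (adjusted p = 0.000268) and Dgat2, which completes triglyceride synthesis, 2.47-fold (adjusted p = 0.00335), in a list with 8 of 25 higher, 3 lower and 14 not called (median 0.33; adjusted p = 0.558 with an estimated correlation). Plin2 fell 3.33-fold to 153 ± 37.0 from 511 ± 208 CPM (adjusted p = 0.00527). Glucose and insulin genes had 7 of 24 higher, 2 lower and 15 not called (median 0.24; adjusted p = 0.209 with an estimated correlation): the growth factor Igf1 rose 4.93-fold to 2550 ± 180 CPM (adjusted p = 0.000418) and Foxo1, a driver of gluconeogenesis, 3.96-fold (adjusted p = 0.00173). Clock genes had 6 of 18 higher, 3 lower and 9 not called (median 0.74; adjusted p = 0.358 with an estimated correlation), with Usp2 247-fold higher (adjusted p = 6.33e-05), Per3, a period gene, 9.10-fold and Tef, a relative of Dbp, 4.92-fold. Kupffer cell markers had 8 of 24 lower and 16 not called (median -1.54, the same with its 3 members at 0 at their floor; adjusted p = 0.637 with an estimated correlation), with complement C1qc 4.74-fold lower (adjusted p = 0.00655). Of 11 nuclear and other long non-coding RNAs 2 were higher, 2 lower and 7 not called (median -0.52), and the list did not pass (adjusted p = 0.693). Among them Malat1, a nuclear RNA, rose to 417 ± 45.9 from 39.8 ± 30.1 CPM (adjusted p = 0.00171), and Mir22hg, a microRNA host gene, had 0 reads in HFD+LYC RNC, at least 86.7-fold lower (adjusted p = 0.000319). Scarna13, a small Cajal body RNA, had 0 reads in HFD RNC and stood at 4.33 ± 2.65 CPM in HFD+LYC RNC, at least 53.0-fold higher (adjusted p = 0.00856). The heart myosin Myh6 had 0 reads in HFD RNC and stood at 43.8 ± 20.8 CPM in HFD+LYC RNC, at least 535-fold higher. Myh7, another heart myosin, had 0 reads in HFD RNC and stood at 29.2, 7.48 and 9.24 CPM in HFD+LYC RNC replicates 1, 2 and 3 (adjusted p = 0.00544, or 0.00431 without replicate 1). The sarcomere protein Ttn rose 312-fold to 45.1 ± 15.0 CPM (adjusted p = 0.000443).

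Of 11,660 genes, 1089 were called higher and 2031 lower in HFD+LYC against HFD RNC, 41.3% had no overlap (chance 10%) and the median over all genes was -0.29. A fit of the 6 libraries alone called 1790 in place of 3120. Among 1825 genes with a mean CPM of at least 50, a limit set after the data were seen, 502 were higher and 497 lower. Of 56 named calls at most 5 were lost without any single library. Without HFD+LYC replicate 1 the log2 changes of Apoa1, Hp and Ahsg were 2.66, 2.35 and 2.19 in place of 3.37, 2.99 and 2.92. Without HFD+LYC replicate 2 that of Rps6 was -5.47 in place of -4.76, and without HFD replicates 1, 2 and 3 those of Malat1, Usp2 and Ttn were 4.19, 9.29 and 9.62 in place of 3.40, 7.95 and 8.28. Of 38 lists, 11 passed, and with an estimated correlation 2 did, both of ribosomal proteins. On the 6 libraries alone, a list test added after the data were seen, 0 of 37 did with an estimated correlation. Simulated libraries with 11,660 genes recovered 2.99%, 17.9% and 54.5% of 2-fold, 4-fold and 8-fold changes.

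HFD+LYC RNC, with reads from 8940 to 10,037 genes, was also set against control RNC, with 14,072 to 14,333. All 80 cytosolic ribosomal protein genes fell (median -4.45, or -4.44 with 1 member at its floor; adjusted p = 0.0225 with an estimated correlation, but 0.0828 on the 6 compared libraries alone), and so did 73 of 76 mitochondrial ribosomal protein genes, with 3 not called (median -4.93 either way; adjusted p = 0.0189 with an estimated correlation, but 0.0828 on the 6 libraries alone). Rpl15 fell 33.6-fold to 7.23 ± 0.823 from 244 ± 9.01 CPM (SE 0.244, adjusted p = 9.7e-06). Lpin1 rose 51.1-fold to 524 ± 95.2 from 10.2 ± 4.74 CPM and Elovl6 22.1-fold, in a synthesis list with 11 of 25 higher, 2 lower and 12 not called (median 0.78; adjusted p = 0.139 with an estimated correlation). Apolipoprotein genes had 16 of 23 higher, 1 lower and 6 not called (median 1.82; adjusted p = 0.307 with an estimated correlation), with Apoa4 72.0-fold and Apoa5, a regulator of plasma triglyceride, 8.50-fold higher. Mgll, monoglyceride lipase, rose 12.99-fold to 1034 ± 265 CPM (adjusted p = 0.000108) among 24 droplet genes with 5 higher, 1 lower and 18 not called (median 0.48; adjusted p = 0.159 with an estimated correlation). Complement genes had 14 of 34 higher and 20 not called (median 1.35; adjusted p = 0.7 with an estimated correlation). Proteasome genes had 2 of 31 higher, 13 lower and 16 not called (median -0.84; adjusted p = 0.845 with an estimated correlation), with Psma4 4.85-fold lower. Interferon response genes had 1 of 27 higher, 8 lower and 18 not called (median -1.24, the same with its 3 members at 0 at their floor; adjusted p = 0.214 with an estimated correlation), with the antiviral Irgm1 22.7-fold lower (adjusted p = 0.00459). The vault RNA Vaultrc5 had 0 reads in control RNC and stood at 5.88 ± 3.28 CPM, at least 72.1-fold higher (adjusted p = 0.0226), and Scarna13, with 0 reads in control RNC, was at least 53.2-fold higher (adjusted p = 0.00845).

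In total 1076 genes were called higher and 1996 lower of 11,660 in HFD+LYC against control RNC, with 44.7% without overlap (chance 10%) and a median over all genes of -0.28. A fit of the 6 libraries alone called 2032 in place of 3072, and genes with a mean CPM of at least 50 gave 500 higher and 491 lower. Of 56 named calls, at most 5 were lost without any single library, and the log2 change of Irgm1 was -6.69 without HFD+LYC replicate 3 in place of -4.51. Vaultrc5 lost its call without control replicate 1, 2 or 3 (adjusted p = 0.0694, 0.0758 and 0.0741). Of 38 lists 14 passed and 2 with an estimated correlation, and on the 6 libraries alone 0 of 37 did with an estimated correlation. Simulated libraries with 11,660 genes recovered 1.49%, 28.4% and 47.0% of 2-fold, 4-fold and 8-fold changes.

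The RNC to mRNA ratio in HFD+LYC against HFD livers rested on HFD+LYC RNC libraries with reads from 8940 to 10,037 genes. All 80 cytosolic ribosomal protein genes fell in ratio (median -3.88, or -3.87 with 1 member at its floor; adjusted p = 0.183 with an estimated correlation) and 73 of 76 mitochondrial ones did, with 3 not called (median -4.55 either way; adjusted p = 0.0264 with an estimated correlation). Rps6 fell 17.9-fold in ratio (SE 0.680, adjusted p = 0.000621). It had mRNA at 151 ± 63.7 against 242 ± 78.7 CPM, as scaled over all 18 libraries, and RNC at 15.9 ± 10.2 against 456 ± 45.5 CPM. The ratio of Apoa1 rose 8.69-fold (adjusted p = 0.00628). It had 97930 ± 68840 against 9883 ± 2291 CPM in RNC and 7987 ± 3282 against 7007 ± 1220 CPM in mRNA. Apolipoprotein genes had 11 of 23 higher and 12 not called (median 1.58; adjusted p = 0.381 with an estimated correlation), complement and coagulation genes 11 of 34 higher and 23 not called (median 1.79; adjusted p = 0.51 with an estimated correlation). Hepatocyte secretory genes had 8 of 18 higher, 1 lower and 9 not called (median 2.04; adjusted p = 0.381 with an estimated correlation). Calr, a chaperone of the endoplasmic reticulum, rose 10.7-fold in ratio (adjusted p = 0.00418) and Malat1 35.1-fold (adjusted p = 0.000266), the latter in a list with 2 of 13 higher, 2 lower and 9 not called, which did not pass. Among the largest rises that the naming rule picked were small non-coding RNAs. Rpph1, the RNA of RNase P, stood at 573 ± 166 against 13.4 ± 18.8 CPM in RNC and 1.34 ± 0.415 against 9.07 ± 8.68 CPM in mRNA (adjusted p = 0.00372). Rmrp, the RNA of RNase MRP, stood at 60.8 ± 35.0 against 0.711 ± 1.15 CPM in RNC (adjusted p = 0.000653), with 2 reads in HFD+LYC mRNA. Lysosome genes had 8 of 30 higher and 22 not called (median 0.65; adjusted p = 0.443 with an estimated correlation), such as the cathepsin Ctsz 6.52-fold (adjusted p = 0.00289). Oxidative phosphorylation genes had a median of -0.09 and a mean of -0.13 while camera placed them above other genes (adjusted p = 0.914 with an estimated correlation), and the median was 0.06 with RLE or DESeq2's scaling.

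The count for this ratio was 440 higher and 1676 lower of 12,872 genes, with 32.6% without overlap (chance 10%) and a median over all genes of -0.41, which DESeq2's scaling moved by 0.129. The count was 1405 without HFD replicate 2 and 1289 without HFD replicate 3, in place of 2116, and 294 higher and 232 lower among genes with a mean CPM of at least 50. Of 45 named calls 17 were lost without HFD replicate 3, 10 without HFD replicate 1 or HFD+LYC replicate 1, 9 without HFD replicate 2 and at most 4 without any other. Log2 changes were 2.42 in place of 3.12 for Apoa1, 2.74 in place of 3.42 for Calr and 2.06 for Ctsz without HFD+LYC replicate 1, and -5.11 in place of -4.16 for Rps6 without HFD+LYC replicate 2. They were 10.56 and 6.76 in place of 8.22 for Rpph1 without HFD replicates 1 and 2, and for Rmrp 15.50 and 9.59 without these and 15.03 and 10.97 without HFD+LYC replicates 2 and 3, in place of 12.07. Against control livers the ratio gave 357 higher and 1549 lower (30.4% without overlap; 776 higher and 1740 lower by DESeq2; median over all genes -0.37, moved by 0.154 with DESeq2's scaling), with 80 of 80 cytosolic and 74 of 76 mitochondrial ribosomal protein genes lower and 11 of 23 apolipoprotein genes higher (adjusted p = 0.116, 0.0123 and 0.325 with an estimated correlation). That count of 1906 was 1209 without control replicate 1 and 1121 without control replicate 3, and 316 higher and 189 lower among genes with a mean CPM of at least 50. Of 37 named calls 10, 5 and 9 were lost without control replicates 1, 2 and 3, 6 without HFD+LYC replicate 1 and at most 2 without any other. Simulated libraries with 12,872 genes recovered 0%, 11.9% and 40.9% of 2-fold, 4-fold and 8-fold changes against HFD and 1.49%, 23.9% and 51.5% against control. Of 38 lists, 12 and 9 passed, 1 in each with an estimated correlation.

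Which transcripts ribosomes carried in the chow-fed liver was asked from RNC against mRNA of the control livers. Nuclear and other long non-coding RNAs were lower in RNC: 5 of 13 were called lower and 8 not (8 over the list alone), with a median of -1.81 (camera, adjusted p = 8.25e-06; adjusted p = 0.375 with an estimated correlation). Malat1 was 18.8-fold lower, at 47.9 ± 8.51 against 902 ± 170 CPM (SE 0.576, adjusted p = 0.006). Kcnq1ot1, an imprinted antisense transcript, was 8.45-fold lower (adjusted p = 0.0227) and Firre, a nuclear RNA, 7.79-fold lower (adjusted p = 0.0301). Among host genes of small nucleolar RNAs 3 of 17 were lower and 14 not called, with a median of -0.59 (adjusted p = 0.375 with an estimated correlation), such as Snhg20 8.44-fold (adjusted p = 0.0335). Oxidative phosphorylation genes were higher in RNC, with 77 of 77 positive, 55 called over the list alone and a median of 1.18 (adjusted p = 0.375 with an estimated correlation). Uqcrb, a subunit of complex III, stood at 555 ± 95.7 against 191 ± 83.3 CPM. Proteasome genes were positive in 31 of 31 (median 0.96; adjusted p = 0.375 with an estimated correlation), cytosolic ribosomal protein genes in 79 of 80 (median 0.93; adjusted p = 0.376 with an estimated correlation) and translation factors in 39 of 45, with 11 called over the list alone (median 0.79; adjusted p = 0.375 with an estimated correlation). The correlation with transcript length computed for each library was -0.439, -0.406 and -0.396 in control RNC. It was -0.108, 0.481 and 0.285 in control mRNA, and the tests did not adjust for length. The kinase Cmpk1, which phosphorylates pyrimidine nucleotides, was higher by 1.51 on the log2 scale (adjusted p = 0.047) and the chaperonin-like Mkks 2.37-fold higher (adjusted p = 0.038), and Spp1, an osteopontin gene marking cholangiocytes, was 3.802-fold lower (adjusted p = 0.0358).

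In control livers 2 genes were called higher and 272 lower of 12,872, and 53.5% had no overlap (chance 10%). With both libraries of a liver as a block 2 were called, both lower. A fit of the 6 libraries alone called 1385 higher and 2497 lower, DESeq2 492 higher and 1689 lower, RLE factors 525 and limma-voom 67 higher and 289 lower. The count of 274 was 13, 0 and 0 without control replicates 1, 2 and 3, 45 without HFD replicate 2, and 799, 1527 and 889 without HFD+LYC replicates 1, 2 and 3. Of 15 named calls 14 were lost with the block, Malat1 kept its call with it, and all 15 were lost without control replicate 2 or 3, those given above with adjusted p 0.274 to 0.7999 and 0.297 to 0.316. Cmpk1, Firre, Kcnq1ot1, Mkks, Snhg20 and Spp1 lost theirs without control replicate 1 (adjusted p 0.0711 to 0.0948), where the log2 change of Firre was -3.57 in place of -2.96, and Cmpk1, Mkks, Snhg20 and Spp1 without HFD replicate 2 (0.0540 to 0.0807). Of 38 lists, 23 passed and 0 with an estimated correlation. DESeq2's scaling moved the median of all genes, -0.07, by -0.147. Simulated libraries with 12,872 genes recovered 4.48%, 40.3% and 77.3% of 2-fold, 4-fold and 8-fold changes.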

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

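The tests of the ratio were planned, and all tests of the 3 patterns weighed here (the ribosomal protein mRNAs, the genes detected and the clock genes) were chosen after the results were seen.

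Some reads entered the total behind the authors' RPKM values but belong to no listed gene, and in 4 RNC libraries their share was above that of every control RNC library (0.765% to 6.31%). These reads made up 13.8% in HFD RNC replicate 1 and 8.22%, 29.9% and 14.2% in HFD+LYC RNC replicates 1, 2 and 3; control mRNA replicate 2 had 23.0%. What they hold is not analysed here.

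By the test of the ratio, the difference between groups was not the same in RNC and mRNA for 2116 genes in HFD+LYC against HFD. In HFD+LYC against control livers this held for 1906 genes. Both comparisons rest on the HFD+LYC RNC libraries, with reads from 8940 to 10,037 genes. An effect of diet and the state of these libraries cannot be told apart here. Further lists stood out because camera called the ratio and the medians in mRNA and RNC had opposite signs, but none of these calls held with an estimated correlation (adjusted p = 0.325 to 0.937). In HFD against control livers the median log2 change of the ratio was -0.11 for amino acid breakdown (0.06 in mRNA, -0.04 in RNC), -0.11 for translation factors (0.04 and -0.13), -0.087 for mitochondrial ribosomal proteins (0.01 and -0.08), -0.24 for cytosolic heat shock proteins (0.23 and -0.08) and 0.57 for host genes of small nucleolar RNAs (-0.21 and 0.28). In HFD+LYC against HFD livers it was 0.31 for fatty acid and triglyceride synthesis (-0.52 and 0.33), 0.36 for the unfolded protein response (-0.49 and 0.32), 1.45 for acute phase proteins (-0.38 and 1.10), 1.79 for complement and coagulation (-0.21 and 1.67), 1.21 for male-biased genes (-0.72 and 0.24), 2.04 for hepatocyte secretory genes (-0.51 and 1.74) and 0.65 for autophagy and lysosome (-0.32 and 0.72). Against control livers it was 1.66 for apolipoproteins (-0.05 and 1.82), 1.42 for acute phase proteins (-0.37 and 1.03), 1.75 for complement and coagulation (-0.46 and 1.35), 1.93 for hepatocyte secretory genes (-0.56 and 1.48) and 0.81 for autophagy and lysosome (-0.03 and 0.98).

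The mRNAs of ribosomal proteins were lower in HFD+LYC than in HFD RNC libraries, with a median of -4.30 over 155 genes at their bound. Genes with names that contain ribosomal but that encode no ribosomal protein, such as kinases of ribosomal protein S6 and factors that process ribosomal RNA, had a median of -4.04 over 20 genes, of which 19 were called lower and 8 had no read in HFD+LYC, while the lowest of 10000 random lists matched on level had -2.18 and the same genes had 0.45 in mRNA; a candidate explanation is that transcripts named ribosomal were removed before counting, although Rrp9 stood at 0.03. A library of few molecules alone is argued against, since the median of the 155 genes lay at percentile 0 of random lists, the lowest of which had -0.87. These lists were matched on level and not on transcript length. The correlation with length computed for each library was -0.103, -0.0373 and 0.00384 in HFD+LYC RNC and -0.367, -0.312 and -0.346 in HFD RNC. Fewer mRNAs of mitochondrial ribosomal proteins on ribosomes is argued against by 5 such proteins under other names, with a median of -0.42 (Gadd45gip1 1.42, Aurkaip1 0.17, Chchd1 -0.42, Dap3 -0.70 and Ptcd3 -1.65). For cytosolic ribosomal proteins this stays open, as 2 of them have other names and they went apart (Rack1 0.28, Fau -2.48, median -1.10), and 52 ribosome assembly genes under other names had a median of -0.33.

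HFD+LYC RNC libraries had reads from 8940, 9567 and 10,037 genes. Fewer reads is argued against, since the 6 control and HFD RNC libraries thinned to the lowest total had 13193 to 13682 genes. The same transcripts missing from ribosomes in each animal is argued against as the source of most losses among genes at 5 to 10 CPM elsewhere. Of 942 such genes with no read in at least 1 of the 3 libraries, 56 or 5.94% had none in all 3. Independent losses would give 18.2 genes, so loss of some of the same transcripts in each animal is not excluded. Genes at higher levels were not covered, such as Mrps33, at 69.4 CPM in control RNC and with 0 reads in all 3 libraries. Few transcript molecules, each read many times, could account for it, since genes with 8 to 20 reads were 6.56 to 11.1 times as many as genes with 1 to 3 reads, against at most 1.35 in the other RNC and 2.43 in all other libraries. Whether lycopene lowered the amount of RNA on ribosomes, or less material was taken, was not tested.

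In mRNA of HFD+LYC against HFD livers, 6 of 9 clock genes that peak in the evening were called higher and all 9 lay above HFD, while of 5 that peak in the morning 2 were called lower and 2 lay above HFD, with medians of 2.50 and -0.95 and a difference of 3.45. In HFD against control livers 1 evening gene was called and the medians were 0.96 and -0.70, a difference of 1.66. A bias with gene length or level is argued against, since the median absolute change of all 19 tested genes of the planned clock list, 1.74, lay at percentile 100 of 10000 random lists matched on both, the highest of which had 1.02. In RNC of HFD+LYC against HFD livers, 5 of 8 tested evening genes were called higher, 1 was called lower and 6 lay above HFD. The 1 called lower was Nr1d2, at -1.40 (edgeR, adjusted p = 0.0134). Of 5 morning genes there, 2 were called lower and 2 lay above HFD. The RNC medians were 2.52 and -2.405. Another time of day at sampling and an effect of lycopene on the clock cannot be told apart, as either could give the 3.45, and the labels give no time of day.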

How the results depend on the processing

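The splits and most alternatives were planned; those with 1 surrogate variable, with a mean CPM of at least 50, without genes named ribosomal, with list tests on the compared libraries alone and with blocked list tests were chosen after the data were seen. In all 10 comparisons, 0 named genes changed direction in an alternative where the gene was called there or in the main fit. Sign changes of genes called in neither fit were not counted, and most genes named in HFD against control were not called. Calls kept under every alternative numbered 1 of 2, 7 of 26 and 16 of 45 named calls in mRNA (HFD against control, HFD+LYC against HFD, HFD+LYC against control), 0 of 1, 47 of 56 and 49 of 56 in RNC, 26 of 45 and 27 of 37 for the ratio with HFD+LYC and 0 of 15 for control RNC against mRNA. Some named genes were not called in the main fit but were in at least 1 alternative. They numbered 13, 27 and 18 in mRNA, 18, 9 and 0 in RNC, 0, 9 and 3 for the ratio and 52 for control RNC against mRNA. The cause of a changed count was not tested where none is given. Replicate libraries of HFD+LYC RNC correlated less in log2 CPM (r = 0.877 to 0.909) than those of control RNC and HFD RNC (r = 0.973 to 0.994). The main fits with RNC libraries estimated spread over all diets together, also for comparisons that did not involve HFD+LYC. Without HFD+LYC replicate 2, control RNC against mRNA gave 1527 calls in place of 274. Fits of the compared libraries alone, given below, left HFD+LYC out and called more genes there and in HFD against control RNC. The counts thus depended on libraries outside the comparison. Filter and scaling changed along with spread, so the part set by spread was not tested apart.

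DESeq2 called 41, 1491 and 1628 genes in the 3 mRNA comparisons in place of 2, 368 and 701, 33 in RNC for HFD against control in place of 1, 1 for the ratio in place of 0, and 2181 in control RNC against mRNA in place of 274. With limma-voom HFD against control gave 1 in mRNA and 0 in RNC (283 at an unadjusted p under 0.05), and with no filter on low counts 6 in mRNA. With RLE factors control RNC against mRNA gave 525. A fit of the compared libraries alone gave 1 and 32 for HFD against control in mRNA and RNC, 1790 and 2032 in RNC for HFD+LYC against HFD and control in place of 3120 and 3072, and 3882 in control RNC against mRNA. With 1 surrogate variable the mRNA counts were 7, 907 and 1914. With a mean CPM of at least 50, where fewer genes are tested, RNC counts were 4, 999 and 991, ratio counts 526 and 505 in place of 2116 and 1906, and control RNC against mRNA 540. Without genes named ribosomal the last count was 181.

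The replicate block gave 3, 1457 and 1425 calls in mRNA, 1, 2734 and 2723 in RNC, 0, 1627 and 1390 for the ratio and 2 in control RNC against mRNA; the cause was not tested. In lists, the animal block gave 14 in place of 6 for the ratio of HFD against control, and 12, 11 and 23 in place of 12, 9 and 23 for the other 18-library comparisons.

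Leaving out 1 library gave 1 to 3, 66 to 606 and 91 to 952 calls in mRNA, 0 to 2, 2107 to 4633 and 2103 to 4605 in RNC, 0, 1289 to 2931 and 1121 to 2734 for the ratio and 0 to 1527 in control RNC against mRNA, and a correlation of 0.299 to 0.677 between HFD changes in mRNA and RNC. At unadjusted p under 0.05, 66 genes in mRNA and 75 in RNC moved in opposite directions under HFD and lycopene, in place of 0; with 2 and 1 genes called for HFD, a count of 0 says nothing about stability.

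With an estimated correlation 0, 0 and 0 lists passed in mRNA in place of 17, 12 and 18, 3, 2 and 2 in RNC in place of 19, 11 and 14, 0, 1 and 1 for the ratio in place of 6, 12 and 9, and 0 of 23 in control RNC against mRNA. On the compared libraries alone it was 0 in all 3 mRNA and all 3 RNC comparisons (lowest adjusted p = 0.2708, 0.7415 and 0.587, and 0.2655, 0.0804 and 0.0828), 0, 1 and 1 for the ratio and 0 in control livers; with the preset correlation those libraries gave 15, 10 and 19, 20, 12 and 15, 6, 12 and 8, and 22. With fry, 0, 2 and 2 passed in mRNA, 3, 19 and 24 in RNC, 0, 14 and 11 for the ratio and 10 in control RNC against mRNA.

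The 10 splits of 6 samples are too few for a share under 0.05. For gene counts the highest other split gave 0 in every comparison, against 2, 368 and 701 in mRNA, 1, 3120 and 3072 in RNC, 0, 2116 and 1906 for the ratio and 274 in control livers; 1 of 10 splits, the real one, reached the real count, and 10 of 10 did where it was 0. Among the control RNC and mRNA libraries, 3 other splits part all 3 livers, as the real one does, and 6 part 1 liver; all 9 gave 0. For lists, real and highest other counts were 17 and 21, 12 and 22, and 18 and 20 in mRNA (6, 7 and 4 of 10 splits as large), 19 and 21, 11 and 14, and 14 and 12 in RNC (5, 3 and 1), 6 and 20, 12 and 17, and 9 and 15 for the ratio (8, 4 and 5), and 23 and 25 in control livers (3). Genes moved in opposite directions numbered 0 in the real and all other splits (10 of 10), and the correlation of HFD changes was 0.600 against at most 0.594 (1 of 10).

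At the depth and spread of these libraries, simulated 2-fold changes were recovered in at most 10.4% of genes in any comparison. Neither depth nor spread was varied. Of the simulated calls in a comparison, 0% to 9.52% fell on unchanged genes, with the highest share in HFD against control RNC. In the HFD+LYC RNC libraries 27.5%, 20.8% and 15.3% of genes at 5 to 10 CPM elsewhere had no read. That share was at most 0.0482% in control and HFD RNC. Whether the simulated counts held such losses was not checked, so the simulated shares may not hold for comparisons with HFD+LYC RNC.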

Other observations

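The counts and levels given here were chosen after the values were seen.

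In RNC of HFD+LYC against HFD livers, in libraries with reads from 8940 to 10,037 genes, several lists held single calls although camera did not call the list. Over all 11,660 tested genes of this comparison, 1089 were called higher and 2031 lower. Of 40 fatty acid oxidation genes, 0 were higher, 10 lower and 30 not called (camera, adjusted p = 0.373). Bile acid synthesis and transport genes had 0 of 24 higher, 9 lower and 15 not called (adjusted p = 0.146). Cholesterol synthesis and uptake genes had 2 of 25 higher, 11 lower and 12 not called (adjusted p = 0.373). Enzymes of amino acid breakdown and the urea cycle had 4 of 36 higher, 11 lower and 21 not called (adjusted p = 0.856). Interferon response genes had 0 of 27 higher, 11 lower and 16 not called (adjusted p = 0.0526), and proteasome genes 2 of 31 higher, 13 lower and 16 not called (adjusted p = 0.0687).

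Some transcripts of heart and skeletal muscle had reads in HFD+LYC RNC libraries. Myh6 stood at 43.8 ± 20.8, Ttn at 45.1 ± 15.0, Myh7 at 15.3 ± 12.1, Klhl41 at 11.6 ± 9.35, Tnni3 at 7.86 ± 6.16 and Mb at 5.52 ± 4.19 CPM (mean ± SD, n = 3). Acta1 had 40, 28 and 0 reads in replicates 1, 2 and 3, Actc1 26, 0 and 7, Myl2 0, 18 and 7, Tnnt2 21, 0 and 0 and Mybpc3 0, 21 and 0, while Ckm, Myl3, Pln, Myh1, Myh2, Myh4 and Tnnt3 had 0 reads there. In mRNA of the same livers Myh6, Myh7 and Mb had 0 reads, and Klhl41 stood at 6.54 ± 5.28 CPM. Tnni3 had 5, 22 and 15 reads there, Tnnt2 9, 7 and 42 and Ttn 2, 3 and 3 in replicates 1, 2 and 3. In control RNC replicate 1 Mb had 6 reads, Tnnt2 9 and Tnni3 5. Des stood at 7.29 ± 3.95 CPM in HFD+LYC, 2.82 ± 2.095 in HFD and 3.13 ± 1.28 in control RNC libraries, and at 12.9 ± 2.25, 6.46 ± 1.09 and 7.56 ± 2.44 CPM in mRNA of the same diets.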
